A study of Homo sapiens with 200 samples.

How the data were processed

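Binding of DNA-associated proteins and histone marks was measured by ChIP-seq on crosslinked chromatin cut with micrococcal nuclease, per the labels' protocols. The cells were HUES64, an established human embryonic stem cell line, and 4 derivatives: mesendoderm (dMS, 12 h of induction), endoderm (dEN, 120 h), mesoderm (dME, 120 h) and ectoderm (dEC, 120 h). Stem cell lines with a knockdown of GATA4 were also taken to dEN and dME. Of 200 samples, 192 had a peak list and 5 of these also had a signal track. The 8 others, 4 whole cell extracts and 4 bisulfite libraries, were not analysed here.

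Reads were aligned with BWA 0.5.7 to human build hg19, per the submitters' processing notes. The peak caller, its threshold and the use of a control are not given in the sources used here. Each deposited peak list held 1 library and gave chromosome, start, end and a score per peak. The score is the authors' own value, with no unit in the files. It was at least 50 in every list, and was used here mainly to rank peaks within a list. The highest score over several lists served to order GATA4 regions and to compare SRF regions. The signal in the 5 deposited tracks was scaled by the authors to nearly the same sum in every track. Its further normalization is not given in the sources used here, so each track was read only against its own genome mean, in 500 bp windows around peak centres on the autosomes. Read depth was not known from the files, and list length (578 to 100778 peaks, median 14160.5) was the measure of depth that remained. Median peak width ran from 68 to 1698 bp between lists. A missing peak is therefore no proof of missing binding, and a longer list has more chances to overlap any other.

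Groups were 1 factor in 1 cell type, from the labels. Libraries whose labels carried a further code (C1, 3d, rd, sort, unsort, ab) formed groups of their own because the labels do not explain the codes. C1 served as the comparison for the shGATA4 lines, which assumes that it has no knockdown. They were left out of the comparisons between cell types unless named. Of 130 groups without a code, 21 had 2 or more libraries and 109 had 1. Factor names were kept as labelled, TCF4 and SMAD23 included. No pair of files was identical. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Date codes in the labels (27 in all) served as the batch.

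Peaks overlapped when they shared 1 bp or more. The similarity of a pair of lists was the Jaccard index, the merged regions holding peaks of both lists over all their merged regions. The mean index of library pairs of the same cell type minus that of pairs of different cell types was tested by permuting cell types among the libraries of a factor. All 15 factors together took 100000 permutations, and each factor alone took an exact permutation test, both two-sided, with Benjamini-Hochberg adjustment over the 15 factors. Breadth was the share of a factor's merged regions bound in 1 to 5 cell types, averaged over all choices of 1 library per cell type. Co-binding of a pair of factors was the observed over the expected number of shared regions within the merged regions of all factors of that cell type, POL2, CTCF and histone marks left out of these regions. Counts and ranks of pairs leave out POL2, CTCF and pairs with a list under 2000 peaks unless stated. The 95% intervals of the ratio came from 1000 resamples of chromosomes. Shares of peaks have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. GATA4 regions of dEN only held a peak in both dEN libraries and in no dME library, and the reverse for dME only. Knockdown values were the share of the C1 library's GATA4 peaks overlapped by another list, and the overlap of SMAD1 and H3K27Ac peaks with these GATA4 peaks, under exact two-sided permutation tests stratified by lineage. The series text gives the lines as the same 3 in both lineages, so line number pairs the dEN with the dME libraries. Line 1 had the highest retained share in dEN and the lowest in dME. With line as a block, the difference between lineages in retained share (26.8 percentage points) had an exact p of 0.25, the smallest this pairing allows.

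Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the computing, and bedtools 2.31.1 served as a check. On simulated lists of 20000 peaks the overlap counts were equal to those of bedtools (8040 and 8013). In simulated factors without cell-type sites, 5% of the tests fell below 0.05. Simulated ratios of 1, 2 and 5 came out as 0.999, 2.00 and 4.99.

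The tests, the groups and most alternatives were fixed before the data were examined. Alternatives covered reciprocal overlap of 50%, the top 50% of each list by score, equal list lengths, coded libraries as replicates, another background and leaving out each replicate. Windows of 500 bp around peak centres, removal of SRF, removal of 2304 regions with peaks of 20 or more factors, equal lists for SMAD1 and H3K27Ac, and the alternatives for GATA4 regions were added after seeing the data. Regions were named by a fixed rule: per cell type the 5 bound by most factors, and among GATA4 regions of 1 lineage the 5 with the highest score. Of the former the highest of each cell type are given. The co-binding pairs, GATA4 partners and factors named in the text were chosen after their values were seen. No annotation or sequence of hg19 was used here, so planned counts of peaks near gene starts, enrichment of lineage gene lists and motif searches were not run, and regions are given by position alone.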

Results

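The series asked how binding sites of regulatory factors change as human embryonic stem cells enter the germ layers. The 192 peak lists covered 37 factors, among them RNA polymerase II (POL2) and the chromatin architecture protein CTCF, and 5 histone marks. HUES64 had 48 libraries of 32 factors and the mesendoderm derivative dMS had 36 libraries, of 28 factors and the marks. Endoderm (dEN) had 51 libraries, mesoderm (dME) 42 and ectoderm (dEC) 15. Values of groups with 1 library have no replicate error, and n is given where there are more.

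Lists of several lineage factors were short in HUES64 and longer in a derivative where the factor is known to act, though this did not hold for all. GATA6, an endoderm and heart regulator, had 2423 peaks in HUES64, 9344 in dMS, 14669 in dEN and 5231 in dME. SOX17, an endoderm regulator, had 2173 peaks in HUES64, 11335 in dMS, 16120 in dEN and 7954 in dME. HAND1, a mesoderm regulator, had 1295 peaks in HUES64, 653 in dMS and 18993 in dME, and SNAI2, a repressor of epithelial genes, had 1716 in HUES64 and 34443 in dME. FOXA2 went the other way between the uncoded lists of HUES64 and dEN, with 10576 and 8394 peaks. The dEN libraries coded rd and 3d held more FOXA2 peaks than HUES64, at 43028 and 36710. FOXA1 had 11733 in HUES64 and 12910 and 17415 in dEN, and T, a mesendoderm regulator, had 4422 in HUES64 and 4646 and 8292 in dMS. The pluripotency factor NANOG had 42573 ± 17963 peaks in HUES64 (SD, n = 4), 32902 in dMS, 43371 ± 24417 in dEN (n = 2), 6909 in dME and 2200 in dEC. CTCF had 80086 ± 8539 peaks in HUES64 (n = 3). Replicates of 1 group differed widely in length, as OTX2 in HUES64 with 17717 to 100778 peaks (n = 4), so list length alone was not tested between cell types.

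Peak lists of a factor were more alike within a cell type than between cell types. Over the 15 factors with replicates, the mean Jaccard index was 0.312 ± 0.141 within (SD over factors) and 0.223 ± 0.141 between. The difference of 0.0883 had a permutation p of 1e-05, two-sided, the smallest the 100000 permutations can give, and 14 of 15 factors had a positive difference. NANOG lists had an index of 0.450 ± 0.0761 within cell types (7 pairs) and 0.235 ± 0.215 between. OTX2, a factor of pluripotent and anterior neural cells, had 0.256 ± 0.102 within (8 pairs) and 0.14 ± 0.0989 between. CTCF lists were alike everywhere, at 0.658 ± 0.0494 within (3 pairs) and 0.555 ± 0.0575 between. SP1, a general promoter factor, had 0.260 within (1 pair) and 0.340 between. In exact permutation tests of single factors, none of 15 passed Benjamini-Hochberg adjustment, 4 had an unadjusted p under 0.05 (CTCF, NANOG, OTX2 and SMAD4) and 8 could not reach 0.05. The lowest adjusted exact p, 0.0714, was that of OTX2 (difference 0.116) and SMAD4 (0.0781). With equal list lengths 3 factors passed (NANOG, OTX2 and SMAD4), and with coded libraries as replicates 4 of 18 (GATA4, GATA6, OTX2 and SMAD4). Under 50% reciprocal overlap the pooled difference was 0.0161, permutation p 0.508. Replicates were all of different dates (37 pairs, mean index 0.346 ± 0.159), as were 195 of the pairs between cell types (0.232 ± 0.183), while the 7 pairs of the same date between cell types had 0.107 ± 0.0712. These 7 were of GATA4, HNF4A, OTX2 and SMAD4 alone, whose mean index between cell types was at most 0.169. The means of unlike factors therefore show no effect of date in either direction.

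**Figure D1:**
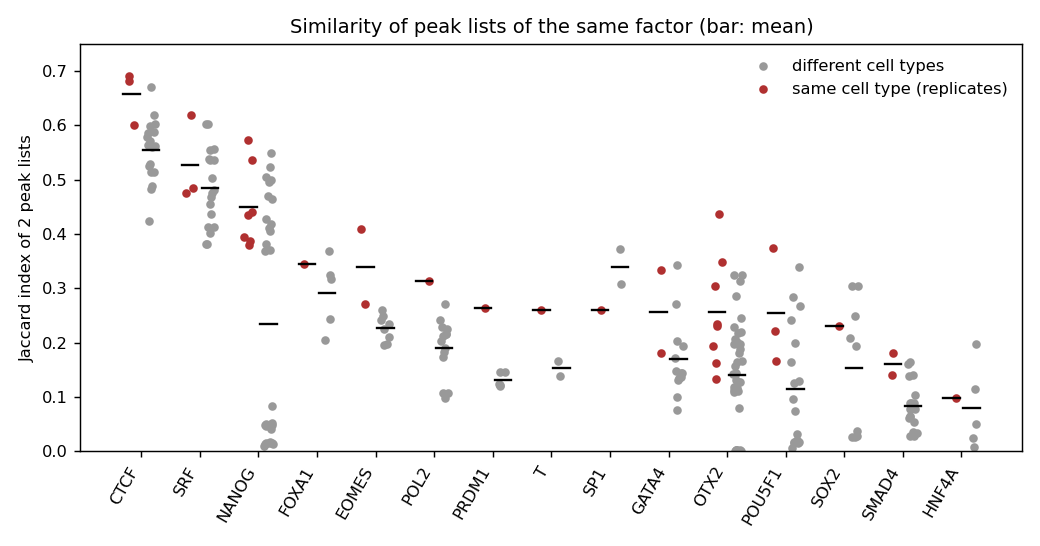
Each point is the Jaccard index of 2 peak lists of the same factor (y axis, no unit), for the 15 factors on the x axis, with replicates of a cell type in red, pairs of different cell types in grey and the mean of each set as a bar. CTCF lies highest, with means of 0.658 within and 0.555 between cell types, and the NANOG pairs between cell types fall apart into a set of 0.369 or more and a set of 0.0831 or less.

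NANOG lists of HUES64 were much alike those of dMS and dEN and little alike those of dME and dEC, while POU5F1 showed no such clear split. NANOG lists of HUES64 had a mean Jaccard index of 0.442 ± 0.0305 with dMS (4 pairs) and 0.451 ± 0.0751 with dEN (8 pairs), against 0.0472 ± 0.00404 with dME and 0.0146 ± 0.00347 with dEC (4 pairs each). The index with dEN was near the mean index of NANOG replicates, 0.450. For POU5F1 (OCT4) the index of HUES64 was 0.297 ± 0.0373 with dEN, 0.163 ± 0.0363 with dMS, 0.0866 ± 0.0492 with dME and 0.0139 ± 0.00610 with dEC (3 pairs each). Its HUES64 replicates had 0.254 ± 0.107 (3 pairs, 0.167 to 0.374), so dEN and dMS cannot be ranked beyond the spread of replicates. Of the POU5F1 peaks of HUES64, 42.0% were found in dEN (38.7% to 45.1%), 19.4% in dMS (15.7% to 22.9%) and 12.8% in dME (5.18% to 18.6%). SOX2, with no library in dEC, gave 0.257 ± 0.0670 with dMS, 0.221 ± 0.0386 with dEN and 0.0277 ± 0.000237 with dME (2 pairs each). Differences between these pairs of cell types were not tested, and the short dEC lists (2200 peaks of NANOG, 1027 of POU5F1) set a low ceiling on the index, as did the dME list of NANOG (6909 peaks). The POU5F1 list of dMS was also shorter than that of dEN (7851 against 15494 peaks), which limits the share found there. Of the NANOG peaks of dME 37.2% and of those of dEC 33.0% were found in HUES64, on average over its 4 libraries. In the same lists 25.9% (dME) and 29.9% (dEC) of peaks lay in regions called for 20 or more factors. Part of the overlap with HUES64 may therefore be such regions. TCF4, a name in use for more than 1 protein and kept here as labelled, had 0.411 between HUES64 and dMS and 0.0390 between HUES64 and dEC. LEF1, which carries the WNT signal to DNA, had 2710 peaks in dMS and 39821 in dME, with an index of 0.00224.

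The lineage factors SOX17, GATA6 and GATA4 shared more sites between dMS and dEN than with dME, a difference that was not tested. The index of SOX17 was 0.329 between dMS and dEN, 0.0939 between dMS and dME and 0.0616 between dEN and dME. GATA6 gave 0.330, 0.127 and 0.121 in the same order, and at most 0.0145 with HUES64. GATA4, which acts in endoderm and heart, gave 0.308 ± 0.0502 (2 pairs), 0.161 ± 0.0168 (2 pairs) and 0.136 ± 0.0485 (4 pairs). The GATA4 replicates had an index of 0.334 in dEN and 0.181 in dME, and the pairs between dEN and dME ran from 0.0758 to 0.195. Of the GATA4 peaks of dEN, 76.8% were found in dMS (71.7% and 82.0% by library).

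Among the 17 factors mapped in 4 or 5 cell types, CTCF had the largest share of regions bound in all of them when any overlap was counted. Of CTCF regions 37.3% ± 1.88 were bound in all 5 cell types (SD over 3 choices of libraries). SRF, the serum response factor, followed with 26.0% ± 1.98, and THAP11, a promoter-binding factor, with 9.90%. SRF peaks lay at CTCF sites in 59.2% to 92.1% of cases by library, so the SRF share may be largely that of CTCF sites. POL2 was shared by all 5 at 4.71% ± 0.127 of its regions, the growth regulator CMYC at 3.86% and the corepressor TRIM28 at 3.21%. The corresponding share was 0.257% ± 0.0522 for NANOG, 0.153% ± 0.0511 for POU5F1 and 0.0274% ± 0.00577 for OTX2. NANOG stood apart in that 27.3% of its regions were bound in exactly 3 cell types. Regions bound in 1 cell type alone made up 81.0% ± 1.63 for SMAD4, 80.5% for SMAD23 and 35.1% ± 2.46 for CTCF, with a median over factors of 70.2%. Over the alternatives the share of CTCF regions in all 5 cell types ran from 4.29% (50% reciprocal overlap) to 52.3% (equal list lengths), and under 50% reciprocal overlap SRF, at 6.25%, ranked above CTCF.

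**Figure D2:**
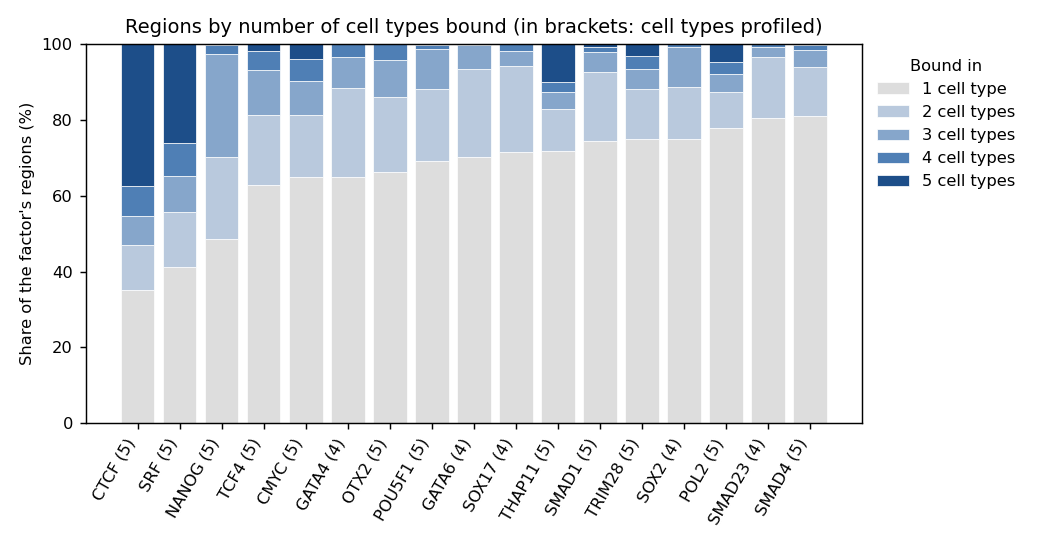
Stacked bars give the share of each factor's regions (y axis, percent) bound in 1 to 5 cell types, for 17 factors on the x axis with the number of cell types profiled in brackets. CTCF and SRF reach 37.3% and 26.0% in all 5 cell types, and NANOG holds 27.3% in exactly 3.

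In HUES64 the known partners POU5F1 and SOX2 shared 6.16 times the number of regions that independent placement gives (95% interval 5.97 to 6.42, library pairs 4.56 to 7.71). NANOG peaks covered 81.3% of SOX2 peaks (74.1% to 90.9% over 8 library pairs, 5.25 times the expected). The ratio of NANOG with POU5F1 was 3.15 (2.46 to 4.44 over 12 library pairs). The zinc finger factor SALL4 with SOX2 had a ratio of 14 (10.1 and 17.9 by library), and REX1 with STAT3 had 13.5 (interval 12.1 to 15.0), although 23.3% of REX1 and 23.1% of STAT3 peaks lay in regions called for 20 or more factors. Of 378 factor pairs in HUES64, pairs with a list under 2000 peaks left out, 309 had a ratio above 1. SRF regions stayed in the merged regions used here, which lowers the expected number for other pairs. Under 50% reciprocal overlap the median ratio over all pairs and cell types fell from 1.82 to 0.395, and single ratios under this rule are to be read against that median. NANOG with POU5F1 then had 0.789 and NANOG with SOX2 0.402.

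In dMS the WNT-linked factor LEF1 lay with SOX2 at 17.1 times the expected number (interval 16.2 to 18.1) and with TCF4 at 11.6 times, and TCF4 peaks covered 72.9% of LEF1 peaks. POU5F1 with SOX2 reached 14.1 (13.5 to 14.9). The signal carriers of the TGF-beta family SMAD23 and SMAD4 had 10.5 (9.51 to 11.5), and SALL4 with SMAD1 had 6.92. The mesendoderm regulators EOMES and T shared 3.87 times the expected number (3.49 to 4.28 over 4 library pairs). GATA4 peaks covered 84.2% of GATA6 peaks in dMS, 3.73 times the expected.

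In dEN the forkhead factors FOXA1 and FOXA2, which open liver and gut chromatin, shared 10.6 times the expected number of regions (8.21 and 13.0 by library). GATA4 with GATA6 had 8.29 (8.09 and 8.48), GATA6 with SOX17 had 6.63 (interval 6.26 to 7.14), EOMES with SOX17 had 4.30 and EOMES with GATA4 had 3.98. POU5F1 with SOX2 had 8.13. In dME the Notch-responsive HEY1 with SMAD4 had 11.9 (10.7 and 13.2 by library), although 38.7% of HEY1 peaks lay in such widely called regions. SMAD1 with SMAD4 had 8.04 (5.53 and 10.5), HAND2 with SOX17 had 7.19 and GATA4 with GATA6 had 4.77 (3.60 and 5.94). GATA4 with HAND1 had 1.35, with 1.98 in the library of the same date and 0.718 in that of another date. LEF1 with TCF4, so close in dMS, had 1.20 in dME, with 0.944 when regions of 20 or more factors were left out and 0.878 against regions of 2 or more factors. In dEC, SMAD4 with TCF4 had 5.48 (4.83 to 6.03), the highest ratio among pairs without a list under 2000 peaks. With such short lists it ranked 9, behind pairs of PAX6, SMAD23 and POU5F1 such as PAX6 with SMAD23 at 29.8 (26.5 to 33.2). The PAX6 and SMAD23 lists share a date, and 25.7% of PAX6 and 46.3% of SMAD23 peaks lay in widely called regions.

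Library pairs of the same date shared more sites than pairs of different dates in each cell type. The median ratios were 3.68 and 1.83 in HUES64, 2.17 and 1.45 in dMS, 3.03 and 1.48 in dEN, 2.62 and 2.11 in dME, and 2.54 and 0.969 in dEC. Pairs named above from libraries of different dates alone were SALL4 with SOX2 and REX1 with STAT3 in HUES64, LEF1 with SOX2 and TCF4, SMAD23 with SMAD4 and GATA4 with GATA6 in dMS, SOX17 with GATA6 and EOMES and EOMES with GATA4 in dEN, and HEY1 with SMAD4, HAND2 with SOX17 and GATA4 with GATA6 in dME.

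A few regions were called for nearly every factor of a cell type. In HUES64 the region bound by most factors, 28 of 30, was on chromosome 8 from 77277546 to 77278459, and 115 of the 192 lists had a peak there. Next came chromosome 11 from 55012869 to 55014096 with 27 of 30 factors. The same places led in dME (chromosome 8 from 77277603 to 77278496, 21 of 23 factors) and in dEN (chromosome 11 from 55011683 to 55014012, 22 of 24). In dMS, chromosome 1 from 149222795 to 149225224 was bound by 21 of 26 factors, and in dEC, chromosome 10 from 39117128 to 39119719 by 11 of 12.

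GATA4 was found with several endoderm factors of dEN at its dEN-only sites, and libraries of dME lay more often at its dME-only sites. Of 57051 GATA4 regions, 5027 were of dEN only, 4297 of dME only and 1891 were in all 4 libraries. GATA6 peaks of dEN covered 78.6% of the dEN-only and 2.56% of the dME-only regions, a difference of 76.0 percentage points (95% interval 74.8 to 77.5). SOX17 of dEN covered 58.3% and 5.26%, EOMES of dEN 36.3% and 50.3% by library against 5.93% and 4.61%, and FOXA2 of dEN 12.9% against 1.91%. HNF4A of dEN did not follow, with 2.80% against 1.68% and 6.88% against 7.68% by library. Nor was the dEN-only side particular to libraries of dEN, since GATA6 of dMS covered 47.6% and 2.14%, SOX17 of dMS 27.5% and 4.12%, EOMES of HUES64 19.1% and 4.19% and FOXA1 of HUES64 14.9% and 4.14%. SOX17 of dME covered 0.975% of the dEN-only and 21.8% of the dME-only regions, SMAD1 0.477% and 20.1%, HAND1 0.259% and 16.5%, HAND2 0.0995% and 14.1%, and TAL1, a blood and vessel factor, 0.0995% and 13.9%. GATA6 of dME covered 5.09% and 22.2%. The dME-only side was likewise not particular to libraries of dME. CMYC of HUES64 covered 0.278% of the dEN-only and 9.38% of the dME-only regions, TAL1 of HUES64 0.159% and 4.33%, SRF of dEN 1.93% and 14.1%, and the promoter mark H3K4me3 of dMS 1.09% and 13.8%. SMAD1 of dEN covered 1.13% and 12.0% in the uncoded library but 24.7% and 4.72% in that labelled C1. The active mark H3K27Ac in the dME library labelled C1 covered 7.92% of the dEN-only and 70.7% of the dME-only regions. In dEN the mark did not favour the dEN-only regions, with 3.18% and 4.49% in C1 and 9.05% and 19.6%, 5.71% and 11.8%, and 3.42% and 6.47% in the libraries labelled shGATA4. GATA4 itself in dMS already covered 94.1% of the dEN-only and 30.7% of the dME-only regions. Some partners share a date with a GATA4 library that defines the side they favoured. These were SMAD1 and HAND1 of dME, SRF and uncoded SMAD1 of dEN and H3K4me3 of dMS for dME-only regions, and GATA6 of dEN for dEN-only regions. SOX17 of dEN and SOX17, HAND2 and TAL1 of dME share no date with the 4 GATA4 libraries. The counts moved with the libraries used, to 2944 and 1972 regions with the top 50% of each list and to 32186 and 25678 with the C1 libraries alone.

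**Figure D3:**
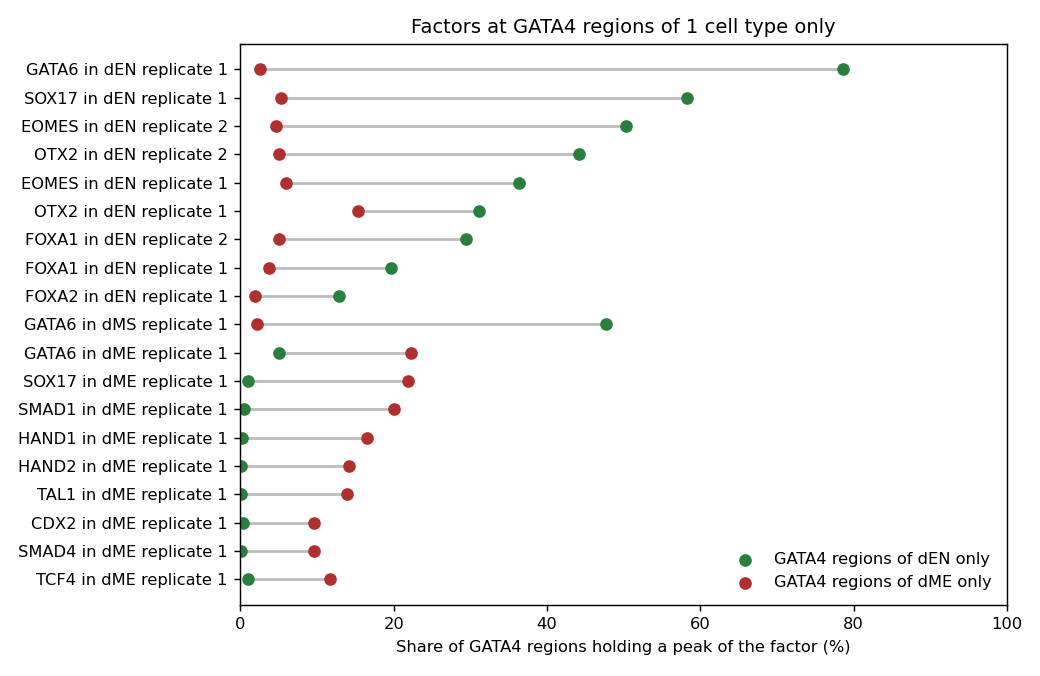
Each line joins the share of GATA4 regions of dEN only (green) and of dME only (red) that hold a peak of the library named on the y axis (x axis, percent). Among the libraries drawn GATA6 in dEN separates them most (78.6% against 2.56%), and the dME libraries from GATA6 to TCF4 lie the other way.

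The strongest GATA4 region of dEN only was on chromosome 16 from 59324260 to 59325237 (highest score 596.22), where EOMES, FOXA1, GATA6, OTX2 and SOX17 also had peaks in dEN. The next 4 were on chromosome 1 from 232488102 to 232488849 and from 193385138 to 193386104, chromosome 9 from 110556306 to 110557122 and chromosome 7 from 158879562 to 158880665, all with GATA6 and SOX17 peaks in dMS and dEN. The regions on chromosomes 16 and 9 also held a GATA6 peak in dME. The strongest of dME only was on chromosome 7 from 150945178 to 150946592 (highest score 1334.78), with peaks of GATA6, HAND1, LEF1, SMAD1, SMAD4 and SNAI2 in dME. It also held peaks of FOXA1, OTX2, SMAD1 and SRF in dEN, of 5 factors in HUES64 and of 4 in dEC. The fourth, on chromosome 8 from 49555857 to 49556674, held peaks of 9 other factors in dME, GATA6, HAND1, HAND2, SMAD1, SOX17 and TAL1 among them, and of none in the other cell types. The others were on chromosome 17 from 20945117 to 20947111, chromosome 22 from 19710492 to 19711999 and chromosome 10 from 36730229 to 36730799. The region on chromosome 17 held peaks of 18 other factors in dME and of 15 in dEN.

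At GATA4 regions the signal tracks gave the same order without peak calls in the tested library. In the unsorted dME library, mean GATA4 signal in 500 bp windows was 8.56 times its genome mean at dME-only regions (95% interval 8.30 to 8.82), 2.51 times at dEN-only regions (2.46 to 2.57) and 11.1 times at regions of all 4 libraries. GATA6 signal in the dEN library coded rd was 9.86 times its genome mean at dEN-only (9.70 to 10.0) and 2.91 times at dME-only GATA4 regions (2.82 to 2.98). That GATA6 library shares its date with a dEN GATA4 library that defines the regions, while the unsorted dME library shares none. For TCF4 and TRIM28 the sets were drawn with the peak calls of the tested library itself. High values at its own peaks and low values at sets without its peaks follow from those calls, so the contrasts are a description only. TCF4 signal in dME was 6.82 times the genome mean at TCF4 peaks of dME only, and 1.25 times (dEC) to 2.12 times (dEN) at those of 1 other cell type. TRIM28 signal in dME was 5.07 times at TRIM28 peaks of dME only, and 1.19 times (HUES64) to 2.25 times (dEN) at those of 1 other cell type. TCF4 signal in dEC separated less, with 2.41 times at TCF4 peaks of dEC only and 1.43 times (HUES64) to 1.75 times (dME) at the others.

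The GATA4 knockdown was examined through the binding of GATA4, of the BMP signal carrier SMAD1 and of H3K27Ac. The labels do not explain C1, and its use here as the comparison without a knockdown is an assumption. GATA4 transcript and protein were not measured in the files used here. In dEN the libraries labelled shGATA4 held no fewer GATA4 peaks than C1, with 57459, 47811 and 49090 against 42477, and in dME they held 11101, 23434 and 38966 against 35842. They overlapped 73.2% ± 3.36 of the C1 peaks in dEN (SD, n = 3) and 46.4% ± 20.2 in dME (n = 3; 26.8%, 45.1% and 67.3%). GATA4 libraries of other dates without a knockdown overlapped 32.1% ± 1.40 in dEN (n = 2) and 30.6% ± 1.79 in dME (n = 2; 29.3% and 31.9%), so that in dME line 1 lay below both. Averaged over the lineages, the libraries labelled shGATA4 lay 28.5 percentage points higher, exact permutation p 0.03, two-sided, where 0.01 is the smallest possible. They share their date with C1, so knockdown and date cannot be separated there, and leaving out any 1 line or library raised the exact p to between 0.0556 and 0.167 at differences of 23.4 to 32.4 points. Retained sites were 26.8 points more frequent in dEN than in dME, exact permutation p 0.1, the smallest that 3 against 3 allows, and 5.88 points (p 0.3) at equal list lengths.

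C1 GATA4 sites missing from the libraries labelled shGATA4 were weaker sites, and GATA6, SMAD1 and H3K27Ac lay there less often. In dEN, 13.8% of C1 peaks were found in none of the 3 lines and 59.0% in all 3, with median C1 scores of 58.75 and 126.09. GATA6 peaks of dEN lay at 0.969% of the former and 48.2% of the latter. In dME 28% were found in none and 22.2% in all 3, with median scores of 59.98 and 222.49, and GATA6 lay at 0.559% and 38.2%. SMAD1 of C1 lay at 3.37% and 22% in dEN and at 10.6% and 56.5% in dME. H3K27Ac of C1 lay at 2.48% and 4.81% in dEN and at 32.8% and 64.4% in dME. The track of the unsorted dME library, of another date than C1, gave a GATA4 signal of 2.88 times the genome mean at sites found in none of the lines, and 4.22, 5.83 and 10.2 times at those found in 1, 2 and 3.

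SMAD1 of dEN lay at C1 GATA4 sites with 54.2% of its peaks in C1 and 26.9% ± 4.39 in the libraries labelled shGATA4 (n = 3; 26.5%, 22.7% and 31.5%). In dME the shares were 55.9% in C1 and 55.8% ± 6.80 (n = 3), a difference that moved with the setting, to -7.28 points with the top 8000 peaks of each list and 8.02 points under 50% reciprocal overlap. Over both lineages the difference was -13.7 percentage points, exact permutation p 0.125, two-sided, and with 16 arrangements no result could pass 0.05. The difference between lineages, -27.1 points, is given without a p, because C1 was 1 library per lineage and its spread is unknown. GATA4 sites with a SMAD1 peak differed by -6.39 points (exact p 0.125). On this measure the lineages were alike, with -6.95 points in dEN and -5.84 in dME. Over the alternatives the dME value ran from -9.26 to -0.361. H3K27Ac peaks at GATA4 sites differed by -3.70 points (exact p 0.3125; -7.08 in dEN and -0.330 in dME, but -1.73 and -8.24 with the top 8000 peaks), and GATA4 sites with H3K27Ac by -2.12 points (exact p 0.62). The dEN C1 list of H3K27Ac was short, at 8653 peaks against 11670 to 54826 in the lines.

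**Figure D4:**
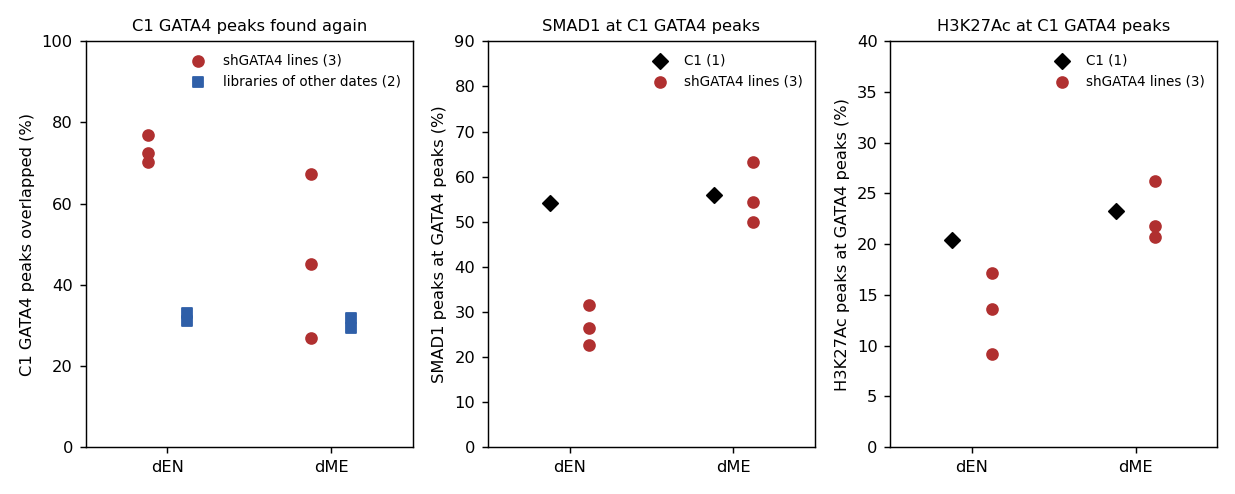
The panels give, in percent on the y axis and by lineage on the x axis, the C1 GATA4 peaks found again (left), SMAD1 peaks at C1 GATA4 peaks (middle) and H3K27Ac peaks at C1 GATA4 peaks (right), each point a library. In dEN the SMAD1 points of the 3 lines (22.7% to 31.5%) lie below C1 (54.2%), while in dME they lie around it (49.8% to 63.2% against 55.9%).

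Factors in dMS differed in the chromatin marks at their sites, and some lay often at the active and the promoter mark alike. Of all factor regions in dMS, 21.4% lay at H3K27Ac, 15.1% at H3K4me1, 15.8% at H3K4me3, 5.22% at H3K27me3 and 3.02% at H3K9me3. SOX2 peaks lay at the active mark H3K27Ac in 68.5% (exact binomial interval 67.2 to 69.8), CMYC in 68.4%, SALL4 in 66.5%, SMAD4 in 64.4%, POU5F1 in 64%, LEF1 in 63.5% and T in 62.7% ± 0.158 (SD, n = 2), against 43.8% ± 2.14 for EOMES (n = 2). At the enhancer mark H3K4me1 lay 41.9% of SMAD1, 41.1% of SALL4 and 34.9% of NANOG peaks. CMYC lay at the promoter mark H3K4me3 in 72.9% (71.6 to 74.1), NR5A2 in 65.0%, THAP11 in 53.3%, SMAD4 in 46.1% and T in 42.7% and 36.5% by library, against 11.0% of SOX2 and 12.9% of LEF1 peaks. NR5A2 also lay at the Polycomb mark H3K27me3 in 25.2% (24.0 to 26.4). TRIM28, which brings H3K9 methylation to silenced repeats, lay at H3K9me3 in 31.6% (30.5 to 32.6), 10.5 times the share of all regions, and at H3K27Ac in 1.13%. GATA4 and GATA6 lay at H3K27Ac in 19.2% and 13.9%, below the share of all regions. The median over factors was 40.3% at H3K27Ac, and 24.6% with the other H3K27Ac library, coded ab, whose list was shorter (20347 against 43421 peaks).

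**Figure D5:**
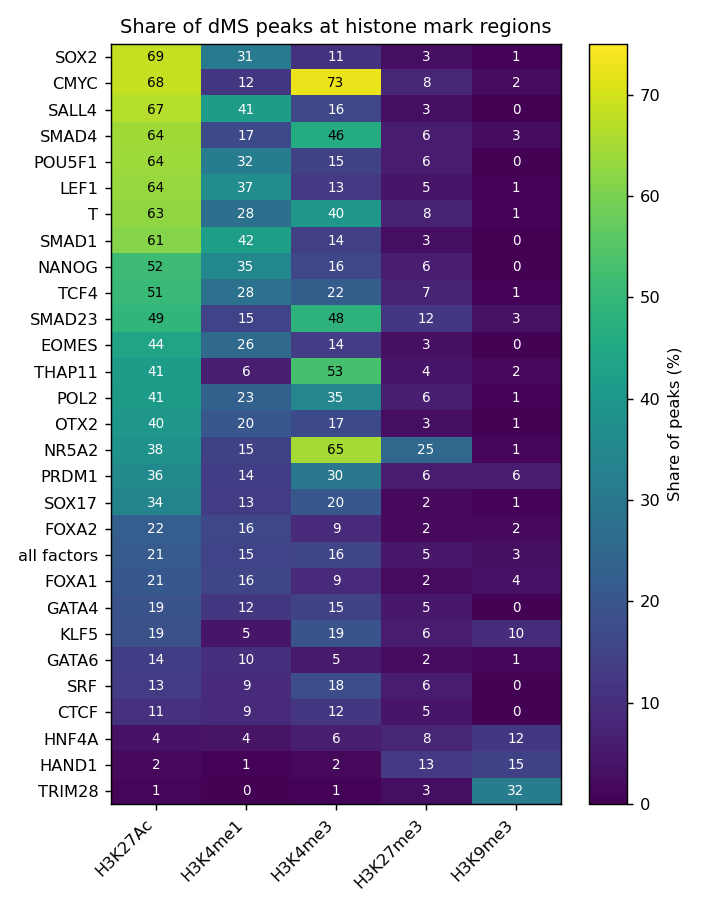
Colour and printed figure give the share of dMS peaks of each factor (y axis, mean over its libraries) that overlap each histone mark (x axis), in percent. SOX2 and CMYC lead at H3K27Ac (68.5% and 68.4%), CMYC at H3K4me3 (72.9%) and TRIM28 at H3K9me3 (31.6%).

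Libraries with a further code were compared with the uncoded libraries of the same factor and cell type. GATA6 of dEN had a Jaccard index of 0.428 with the library coded 3d and 0.414 with that coded rd, and GATA6 of dME 0.187 with rd. GATA4 of dME had 0.224 with the sorted and 0.297 with the unsorted library, against 0.181 between its replicates, and sorted and unsorted cells had 0.363 with each other. FOXA1 3d, with 92619 peaks, had 0.137 with the uncoded dEN lists, against 0.345 between these, yet covered 87.1% of their peaks, and at equal list lengths its index was 0.412. SMAD1 of C1 in dEN had 0.0267 with the uncoded SMAD1 library. At equal list lengths the median index of the coded libraries was 0.412, against 0.224 with the lists as deposited.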

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

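The comparison of SRF with other long lists, the equal-length test of SMAD1, the permutation of date codes and a counting limit on H3K27Ac peaks were chosen after the results were seen, as were the count of SRF regions in widely called regions and the comparison of their scores. The first OTX2 library of HUES64 held 100778 peaks, far from the 17717, 18480 and 27254 of the other libraries in its group. It was the 1 of 6 values looked at in groups of 4 or more libraries that stood apart, and chance singles out about 1 in 20 groups. H3K27Ac at C1 GATA4 sites moved in opposite directions in the 2 lineages, with every dEN library labelled shGATA4 above C1 and every dME library below it. The share of GATA4 sites with H3K27Ac differed by 11.7 percentage points between the lineages, 1 of 6 values looked at this way. It is given without a p, because C1 was 1 library per lineage and its spread is unknown. The dEN part rested on list length, since with the top 8000 peaks of each list it was -0.0863 points.

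SRF peaks lay at CTCF sites of the same cell type in 81.4% ± 11.4 of cases (SD over 7 libraries, 59.2% to 92.1%). Long lists in general do not account for this, because the HUES64 mean of SRF was 2.14 times the highest share in 18 other long HUES64 lists (CMYC, 37.9%). Weak CTCF background under stronger SRF sites is argued against as well: in 0 of 7 libraries did the top 1000 peaks lie at CTCF less often than the whole list, and their share was 97.4% to 99.6%. Of 36186 regions shared by 5 or more of the 7 lists 228 had no CTCF peak, 19.3 times the 11.8 that chance placement gives. SRF sites of their own cannot be told apart here from CTCF sites just under the peak threshold, because chance placement does not allow for such sites, which would be shared by the lists too. The median highest score of these regions was 487.32, below the 574.02 of regions at CTCF (both without regions called for 20 or more factors), and 41 of the 228 lay in such widely called regions. SRF libraries 2 and 3 of HUES64 and those of dME and dEC share a date with a CTCF library of their cell type. Without such a date the share at CTCF sites was 81.5% (HUES64 library 1), 59.2% (dEN) and 89.4% (dMS), so high shares were also seen there. Cross-reaction of the antibody (1 antibody and lot in all 7 libraries) and binding of SRF next to CTCF stay open as possible explanations and were not tested.

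SMAD1 of the dEN libraries labelled shGATA4 lay less often at C1 GATA4 sites than SMAD1 of C1, although GATA4 peaks in these libraries were no fewer than in C1. List length does not account for it, since with the top 9000 peaks of every list the highest line was still -27.2 points from C1 (59.4% in C1, 25.4% to 32.2% in the lines). The loss of SMAD1 did not follow the loss of GATA4 peaks: SMAD1 was kept no more often where the line kept the GATA4 peak, with a median difference of -6.09 points and 6 of 6 line and score strata at or below 0. Weaker GATA4 binding at sites that kept a peak could not be seen this way. GATA4 score, which was lower at C1 sites found in none of the lines, was not made equal. Cells that kept the chromatin of HUES64 cannot be told apart from a knockdown effect, because H3K27Ac peaks at NANOG sites of HUES64 only were too few (5 of 8000 in C1 and 7 to 9 in the lines, a difference of 0.0333 points). SMAD1 of the lines lay more often than C1 at NANOG, POU5F1 and SOX2 sites, as given under the other observations, which goes with this explanation. The same rise was seen at CTCF, SRF and POL2 sites, so it does not decide the question. An effect of the knockdown on SMAD1, or a difference of the single C1 library, may lie behind the lower share at C1 GATA4 sites and stays untested. SMAD1 of C1 had a Jaccard index of only 0.0267 with the uncoded dEN library.

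Different factors profiled on the same date shared more sites than factors profiled on different dates. In 10000 permutations of date codes within cell types the observed difference (0.93 on the log2 scale) was never reached, one-sided p 0.0001, the smallest these can give. Related factors profiled together are argued against as all of it. For 138 fixed factor pairs with both kinds of library pair the same-date ratio was still 0.58 higher on the log2 scale (95% interval 0.44 to 0.73, 106 pairs above 0). The pairs reuse the same libraries, so the intervals here do not cover a single unusual library or date and may be too narrow. Shared list length is argued against, as the top 2000 peaks of every list gave 0.85 (0.60 to 1.12). What the date stands for, such as cells, chromatin or sequencing shared by the libraries, may account for it and stays open; no biological explanation was tested.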

How the results depend on the processing

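Windows of 500 bp, removal of SRF, removal of regions with peaks of 20 or more factors, the top 8000 peaks and the alternatives for GATA4 regions were chosen after the data were seen. Of the alternative values of the main comparisons 96 were counted as the same, 19 changed in size, 8 lost the threshold and 2 turned direction. Values with a test were counted by direction and side of the threshold, not by size. The difference between lineages in retained GATA4 sites counted as the same from 5.88 to 37.6 points. Of the 96, 55 were alternatives of the pooled difference in similarity. Values of single factors, factor pairs and lineages were less stable, with 163 the same, 6 stronger, 144 changed in size and 23 turned in direction. Among the turns are the median co-binding ratio and 8 pair ratios under 50% reciprocal overlap, which lowered the median over all pairs too, so that a ratio below 1 there shows no change particular to a pair. For these the cause was not tested. By its rule, 50% reciprocal overlap loses matches between peaks of unlike width, and median widths of factor lists ran from 68 to 1073 bp. Depth was unknown, list length limited every overlap, and 109 groups had 1 library.

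Under 50% reciprocal overlap the pooled difference in similarity was 0.0161, the median share of regions in 1 cell type 84.6% and the median co-binding ratio 0.395. SRF (6.25%) then ranked above CTCF (4.29%) in the share of regions bound in all 5 cell types. Differences of single factors turned negative for CTCF (-0.0633), GATA4 (-0.00219), HNF4A (-0.0240), PRDM1 (-0.0376), SMAD4 (-0.0169), SOX2 (-0.0136) and SRF (-0.0716). Of the 28 pairs followed, 8 fell below 1: NANOG with POU5F1 (0.789) and SOX2 (0.402) in HUES64, NANOG with POU5F1 (0.715) and EOMES with SMAD23 (0.445) in dMS, POU5F1 with SOX2 (0.711) in dEN, and in dME GATA4 with HAND1 (0.436) and TAL1 (0.946) and LEF1 with TCF4 (0.344). GATA4 sites with H3K27Ac then differed by 0.117 points, and by 0.161 in dME. With 500 bp windows the pooled difference in similarity kept its size.

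At equal list lengths 3 factors passed in similarity, FOXA1 (-0.000105) and SRF (-0.00241) turned negative, 65.2% of regions were in 1 cell type and the median index of coded libraries was 0.412. With coded libraries as replicates 4 factors passed and FOXA1 had -0.0668. The top 50% by score gave 67.1% in 1 cell type, a median ratio of 1.42, 2944 dEN-only and 1972 dME-only GATA4 regions and 36.5% at H3K27Ac in dMS, against 24.6% with the mark library coded ab. Regions of 2 or more factors as background gave a median ratio of 1.29, with GATA4 and HAND1 at 0.857 and LEF1 and TCF4 at 0.878 in dME. Without regions of 20 or more factors the median ratio was 1.42, and LEF1 with TCF4 in dME 0.944. With SRF removed from the background, 16 of the 28 pairs followed changed in size, 12 stayed the same and 0 turned. The C1 libraries alone gave 32186 and 25678 GATA4 regions. With the top 8000 peaks GATA4 sites with H3K27Ac in dEN differed by -0.0863 points.

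Leaving out each replicate in turn kept the pooled difference in similarity at 0.0827 to 0.100. It gave 23.4 to 32.4 points for C1 GATA4 peaks found again, 5637 to 10957 dEN-only regions (10957 without the first dEN library) and 4770 to 23420 dME-only regions (23420 without the second dME library). With line as a replicate block the difference between lineages, 26.8 points, had an exact p of 0.25; the block changed no call. Counts of peaks near gene starts, gene list enrichment, GATA4 gene lists and motif searches were not run, nor were their alternatives.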

Other observations

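The partner sites of SMAD1 were looked at only after its lower share at GATA4 sites in the lines was seen, and these values are a description of the libraries labelled shGATA4 and C1. In dEN, SMAD1 of the 3 lines lay more often at NANOG sites than SMAD1 of C1. For NANOG library 4 of HUES64 the share of SMAD1 peaks was 64.5% ± 3.64 in the lines (SD, n = 3) and 39.6% in C1, and for NANOG library 1 of dEN 65.2% ± 3.15 and 41.9%. At POU5F1 sites (library 3 of HUES64) it was 32.5% ± 1.93 and 18.2%, at SOX2 sites (library 1 of HUES64) 29.3% ± 3.00 and 17.4%, and at SMAD1 sites of HUES64 46.2% ± 3.44 and 27.7%. The rise was broad, as it was also seen at sites without a known link to pluripotency: 12.0% ± 1.81 and 8.25% for CTCF library 1 of HUES64, 19.6% ± 0.847 and 13.2% for SRF library 1 of HUES64, and 22.8% ± 0.339 and 15.6% for POL2 of dMS. The endoderm sites moved the other way, with 8.98% ± 1.72 and 23.9% at GATA6 sites of dEN, 19.1% ± 2.89 and 34.5% at SOX17 sites and 6.80% ± 1.18 and 14.2% at FOXA2 sites. With the top 9000 peaks of every list the values at the same NANOG sites of dEN were 73.6% in the lines and 44.3% in C1. Peak width was not made equal. Median widths of SMAD1 peaks in dEN were 433, 430 and 425 bp in the lines and 275 bp in C1. In dME they were 372, 341 and 485 bp in the lines and 196 bp in C1. Wider peaks have more chances to overlap any site, and how much of the rise came from width was not tested. In dME the lines and C1 lay close together, with 19.7% ± 2.27 and 17.1% at NANOG library 4 of HUES64 and 6.52% ± 1.05 and 5.49% at POU5F1 sites. These differences were not tested, and C1 was 1 library per lineage.

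Some HUES64 lists of factors known for germ layers lay often at sites of dMS, reached after 12 h of differentiation. Of the FOXA1 peaks of HUES64 87.2% were found in dMS, of the GATA4 peaks 74.5%, of the FOXA2 peaks 58.8% and of the SOX17 peaks 50.2%, against 33.3% of the T peaks (2 library pairs), 19.4% of PRDM1, 6.02% of HAND1, 3.91% of HNF4A and 3.10% of GATA6. List length played a part that was not separated, since FOXA1 and GATA4 had the long dMS lists (40123 and 40222 peaks) and HAND1 and HNF4A short ones (653 and 3422). Of the EOMES peaks of HUES64 49.5% were found in dMS and 51.7% in dEN (2 library pairs each). OTX2 in dME, with 578 peaks, shared 7.57% of these with HUES64 and 19.4% with regions called for 20 or more factors. PAX6, an eye and neural regulator, had 1562 peaks in dEC, of which 25.7% lay in such regions, and 2313 in the dEN library coded 3d.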
